A study of Mus musculus with 4 samples.

How the data were processed

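RNA of sorted LSK cells from mice labelled Ezh1 knockout (2 arrays) and control (2 arrays) was hybridised to single-colour Agilent mouse arrays. Per the labels' protocols, total RNA had integrity numbers of at least 9, and the small amounts available were amplified across the whole transcriptome with the WTA2 kit, stopping shortly after the plateau seen in real-time PCR. The labels list 16, 16, 19 and 18 amplification cycles for the 4 samples without naming which sample each belongs to, so cycle number was assigned to no array. If the cycles followed the order in which the samples are listed, they would part the groups completely, and every difference between the groups could then stem from amplification as well as from genotype. Per the labels, the amplified cDNA was labelled with a platinum-linked Cy3 dye that couples preferentially to guanine. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction, whose version and signal column are not given in the sources used here. Amplification and guanine-dependent labelling can both change the signal of a probe by its sequence, which limits comparisons between probes. Comparisons of 1 probe between arrays are free of this only where the arrays were amplified alike, and the listed cycles differ.

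The deposited signal table holds 1 intensity per probe and array on a linear scale, with no negative values, flags, background columns or control spots. The authors' deposited comparison table holds an unadjusted p-value per probe and, per the file headers, an absolute fold (ratio of normalized intensities, not on a log scale) with its direction in a separate column. Set against the intensities, that fold equalled the difference after shifting each array by its 75th percentile, and that p-value equalled a plain equal-variance test on the 4 log2 values (median relative difference 0.137%). A deposited value table in log2 units was checked too. It gives values for 16370 probe names, with medians of -2.59 and -2.05 in the knockout-labelled arrays and -3.34 and -2.54 in the control arrays. All of its entries matched the 4 shifted log2 intensities of some probe within 0.01, but only 3.73% matched those of their own probe name. By probe name its values correlated with the log2 intensities at r of 0.0690 to 0.0914 across probes. For genes with exactly 2 probes, the mean levels of both probes correlated at 0.559 by the names of the signal table and at -0.01 by those of the value table. Ribosomal protein probes lay 6.79 above the median of all probes in the signal table and 0.22 above it in the value table. The names of the signal table were therefore used, and the value table was not used by name.

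Of 55677 probes, 33323 carried a gene symbol and 22354 did not; the latter entered only the test of every probe. Symbols were updated through a RefSeq gene table of mouse assembly GRCm38.p6, used for names and neighbouring genes only: 26761 probes were named by accession, 3814 by symbol and 638 by a synonym held by 1 gene, and 2110 kept the symbol of the file. This gave 24231 genes, 7076 of them with several probes, of which the brightest by mean over the 4 arrays stood for the gene. For genes with exactly 2 probes, the log2 differences of both probes correlated at only 0.413. The value of the brightest probe therefore need not hold for a gene's other probes. The log2 intensity minus the array's 75th percentile was analysed. A gene entered where its probe lay above the array's 30th percentile in both arrays of at least 1 group, which left 17090 genes. Arrays have no depth in counts; the number of arrays limits the precision.

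Knockout-labelled and control arrays were compared with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend; prior degrees of freedom 4.21, residual degrees of freedom 2) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes whose groups did not overlap and differed by at least 2-fold were counted as a description. The 44 gene lists, among them markers of other marrow cells, were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma's camera at an inter-gene correlation of 0.01 with adjustment over 43 lists, and again with an estimated correlation and with limma's fry. Members were also adjusted over the list alone, without adjustment across the lists. Sums and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

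Genes were named by a rule fixed at the same time. Ezh1 and the other PRC2 subunits were always named. The 12 largest differences in each direction among genes with an adjusted p under 0.05 and groups without overlap came next, filled where fewer passed with genes of an unadjusted p under 0.01 and groups without overlap, given as values. No gene passed the first part, and 157 genes that were higher and 29 that were lower could fill it. Predicted genes, Riken clones and symbols starting with Gm, LOC or ENSMUS were left out of these 24. In each list every member with an adjusted p under 0.05, over all genes or over the list alone, was named, up to 6, or else the 2 members with the largest differences. Some members that this rule names are not reported here. Cdkn2a, Cdkn1a, Cdkn1c, Ezh2, Eed, Suz12, Kit, Ly6a, Flt3 and Il7r were always named.

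The fit was tested on simulated data for the comparison of knockout-labelled with control arrays, with 200 of 17090 genes changed in each of 20 rounds and noise drawn independently for each array. It recovered 9.40% of genes changed by 1 log2 unit, 59.1% of those changed by 2 and 74.8% of those changed by 3, and 13.9% of its calls were false, above the 5% aimed at. A list shifted by 0.6 was called in 20 of 20 rounds with the preset correlation and in 0 with an estimated one, which with 4 arrays has little power. The simulated noise held no pattern shared between arrays, unlike the real arrays. These rounds therefore do not show that the preset correlation suits the real arrays. Alternatives were quantile and median scaling, 50 added to the intensities, no dim filter, a filter at the array median, the mean over a gene's probes, every probe on its own, no mean-variance trend, the replicate number as a block, array weights, a plain equal-variance test with a fold minimum, the 2 other list tests, and each array left out in turn.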

Results

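LSK cells are mouse bone marrow cells without lineage markers that carry Sca-1 and Kit, the fraction that holds hematopoietic stem cells and multipotent progenitors. Gene expression in sorted LSK cells was measured on 4 single-colour (Cy3) Agilent mouse arrays. By their labels, 2 arrays held RNA of mice with a knockout of Ezh1, a histone H3 methyltransferase of Polycomb repressive complex 2 (PRC2), and 2 held RNA of control mice, all on a C57BL/6J background. The question was which genes differ in expression when Ezh1 is missing. Each array gave signals for 55677 probes, and 17090 genes passed the filter on dim probes and were tested. The 75th percentile of the signal was 1095 and 1690 intensity units in the knockout-labelled arrays and 1594 and 1531 in the control arrays. The arrays differed more in the width of their signal distribution. Its interquartile range on the log2 scale was 4.93 and 3.83 in knockout-labelled replicates 1 and 2, and 5.95 and 4.22 in control replicates 1 and 2. Across genes, Pearson's r was 0.949 between the knockout-labelled arrays, 0.924 between the control arrays and 0.867 to 0.961 between arrays of different groups. The SD of the log2 difference between arrays was 0.76 and 1.05 within the groups and 0.63 to 1.34 between them. Genes are not independent replicates, and these correlations carry no test. The labels do not say whether replicates came from separate mice, so p-values of single genes measure the spread between these arrays only. Having 2 arrays per group limits the precision of every value.

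The targeted gene was examined first. Its probes went different ways, and the brightest did not read lower in the knockout-labelled arrays. That probe, of 4, A_55_P2155942, read 0.92 and 1.14 in the knockout-labelled arrays and 0.74 and 0.78 in the control arrays, in log2 units relative to each array's 75th percentile. Its log2 difference was 0.27 ± 0.22 (SE, n = 2 per group; limma adjusted p = 0.717), with a 95% interval from -0.27 to 0.82. It was 0.16 without knockout-labelled replicate 2, and lay between 0.25 and 0.39 without each of the other arrays. After scaling to the array median it was 0.05. Probes A_55_P2082869 and A_55_P2017086 differed by -0.09 and 0.13. The dimmest probe, A_55_P2017090, read -2.38 and -4.22 in the knockout-labelled arrays against -1.95 and -2.35 in the controls, lower in both knockout-labelled arrays. Its reading in knockout-labelled replicate 2 lay under the array's 30th percentile, so the size of its difference is not given; the mean of the probes, which takes in this reading, differed by -0.21. With every probe tested on its own, the adjusted p of the 4 probes lay between 0.685 and 0.902. The labels do not give the deleted part of the gene, and a probe outside it checks nothing, so the genotype was not checked by these values and the groups are called knockout-labelled and control throughout.

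**Figure D1:**
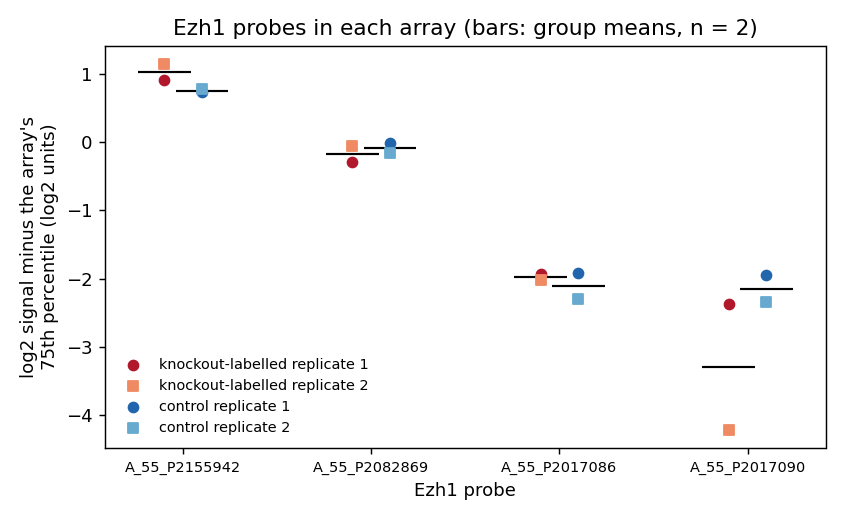
Signal of the 4 Ezh1 probes in each array, in log2 units relative to the array's 75th percentile, with points for arrays and bars for group means (n = 2). The brightest probe lies at 0.92 and 1.14 in the knockout-labelled arrays and at 0.74 and 0.78 in the control arrays.

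Granulocyte genes made up much of the upper end of the comparison. Of the 12 genes with the largest positive differences named by the fixed rule, 7 belong to the list of neutrophil markers: Ltf (lactoferrin), Ngp, S100a9 and S100a8 (the subunits of calprotectin), Chil3, Camp (the cathelicidin antimicrobial peptide) and Retnlg. They read 5.24-fold (S100a8) to 10.3-fold (Ltf) higher in the knockout-labelled arrays. No single gene passed the threshold over all genes. With limma, 0 of 17090 genes had an adjusted p under 0.05, and the smallest was 0.127. At an unadjusted p under 0.05 there were 1198 genes, 737 higher and 461 lower, against 854.5 for independent arrays without differences. The splits that mix the groups gave 2084 (arrays with replicate number 1 against number 2) and 30, so 1198 is no measure of an excess. At an unadjusted p under 0.01 there were 253, of which 222 were higher. A plain equal-variance test gave 246 genes with an unadjusted p under 0.05 and at least a 2-fold difference, 206 of them higher, and 0 after adjustment. The differences below are therefore given as values, except where a gene list or a count adjusted over the list alone passed its test. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333. The count of 0 depended on the processing: it was 104 after scaling to the array median and 142 with the replicate number as a block, which the labels do not state as a pairing. It also depended on which array was left out: limma then called 2 genes without knockout-labelled replicate 1, 114 without knockout-labelled replicate 2, 11 without control replicate 1 and 626 without control replicate 2.

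By size alone, 740 genes lay higher and 173 lower by at least 2-fold in the knockout-labelled arrays with values of both groups that did not overlap. Groups did not overlap in 40.3% of genes, where chance gives 33.3% if arrays vary independently. The split that sets both arrays with replicate number 1 against both with number 2 parted 46.4% of genes and gave 1999 by the same rule, and the remaining mixed split parted 13.3% and gave 90. The balance depended on the scaling: 560 genes were higher and 419 lower after quantile normalization, and 493 and 473 after scaling to the array median, which moved the median difference of all genes from -0.02 to -0.24. The number lower was 683 without knockout-labelled replicate 1, 276 without knockout-labelled replicate 2, 320 without control replicate 1 and 422 without control replicate 2. The number higher was 2426 without knockout-labelled replicate 1 and 2636 without control replicate 2. It was 703 without knockout-labelled replicate 2 and 678 without control replicate 1, both under the 740 of all arrays. With 1 array against 2, chance parts 66.7% of genes, so larger counts can lie partly in the construction of these comparisons. That alone does not account for the number higher, which grew in only some of them.

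Among the other 5 genes at the upper end were Chd7, a chromatin remodeller, and Wfdc21. Chd7 differed by 3.37 ± 0.47 (SE; limma adjusted p = 0.248) and Wfdc21 by 2.55 ± 0.29 (adjusted p = 0.187). Psg28 differed by 3.10, an immunoglobulin light chain segment of the Igkv4 family by 2.59 and the cytochrome P450 gene Cyp3a13 by 2.41, each with an adjusted p of 0.669. Chd7 in control replicate 2 and Slc15a2 in knockout-labelled replicate 2 lay under the array's 30th percentile, so their sizes and places are uncertain. At the lower end, the peptide transporter gene Slc15a2 differed by -3.52 ± 0.93 (SE; adjusted p = 0.669), with knockout-labelled values of -0.88 and -4.02 that lay far apart. Rsad2, which encodes the interferon-induced antiviral protein viperin, differed by -2.29 ± 0.21 (SE; adjusted p = 0.127), a 4.89-fold lower signal, with 0.24 and 0.41 against 2.69 and 2.54. The other 10 genes at this end were Zfp868, Clec4e, Ccnb1ip1, Xkr6, Marveld2, AU023617, Igsf10, AW556253, Fastkd3 and Sval1. Their differences ran from -1.79 (Zfp868) to -1.14 (Sval1), with an adjusted p of 0.545 for Xkr6 and 0.669 for the rest.

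Of 43 gene lists that could be tested, 7 passed camera at an adjusted p under 0.05, 5 upward and 2 downward, all with the preset inter-gene correlation of 0.01. Such a camera p sets the genes of a list against other genes under that assumed correlation. It does not measure the spread between arrays. By fry, which draws on that spread, no list passed, and the neutrophil markers had an adjusted p of 0.204. The neutrophil marker list rose, with a median log2 difference of 2.39 (camera adjusted p = 5.11e-14; adjusted p = 0.950 with an estimated correlation). Of its 15 measured genes, 13 were higher and 2 lower. Over all genes none of them was called, and adjusted over the list alone 11 rose and 4 were not called. The increases were 3.12 ± 0.28 (SE) for Ngp, 3.11 ± 0.28 for S100a9, 2.39 ± 0.22 for S100a8, 3.36 ± 0.34 for Ltf, 2.43 ± 0.27 for Retnlg and 2.21 ± 0.27 for Lcn2, the siderophore-binding protein lipocalin 2. Their p adjusted over the list alone lay between 0.000136 and 0.000343. In signal, S100a9 read 3.93 and 3.80 in the knockout-labelled arrays against 1.11 and 0.40 in the controls. The members not called were Padi4 (-0.54), Itgam (-0.34), Cxcr2 (0.53) and Cd177 (0.67). The probes of Itgam disagreed, since its dimmer probes differed by 0.72 and 0.87. The list's adjusted p stayed under 0.05 without each array in turn.

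Genes of early granulocyte and monocyte progenitors rose as well, with a median of 0.59 (camera adjusted p = 8.03e-12; adjusted p = 0.950 with an estimated correlation). All 19 measured members were higher, 17 of them without overlap between the groups, and no member is on the neutrophil list. Adjusted over the list alone, 6 rose and 13 were not called, and over all genes none was called. Those called were the azurophil granule protease genes Elane (1.03 ± 0.18, SE), Prtn3 (1.05 ± 0.26) and Ctsg (0.59 ± 0.18), the granulocytic transcription factor gene Cebpe (1.28 ± 0.30), Ms4a3 (0.86 ± 0.21) and the receptor gene Csf1r (0.73 ± 0.19). Mpo, the myeloperoxidase gene, differed by 0.49 ± 0.22 and was not called. The shift stood beside the 2.39 of the neutrophil markers, and its adjusted p stayed under 0.05 without each array in turn.

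**Figure D2:**
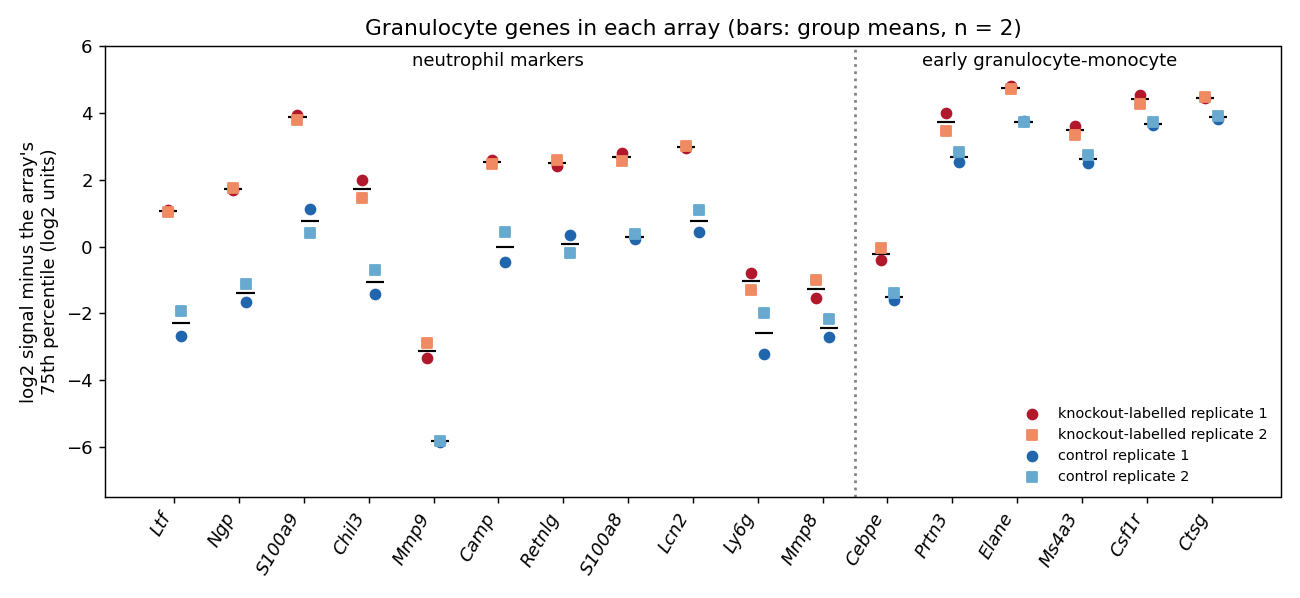
Neutrophil marker and early granulocyte-monocyte genes with a p under 0.05 adjusted over their list alone, in log2 units relative to each array's 75th percentile, with points for arrays and bars for group means (n = 2). In each of these genes both knockout-labelled arrays lie above both control arrays, as for Elane, whose log2 difference was 1.03.

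Early lymphoid genes rose, with a median of 0.62 (camera adjusted p = 0.000407; adjusted p = 0.950 with an estimated correlation). Of 19 measured members 15 were higher, and none was called over all genes or adjusted over the list alone. Ebf1, a transcription factor of B cell commitment, differed by 2.36 ± 0.73 (SE), and Cd79a, a chain of the B cell receptor complex, by 1.70 ± 0.50. This call rested on 1 array: without knockout-labelled replicate 1 the median was -0.06 and the adjusted p was 0.428. The interleukin 7 receptor gene Il7r differed by 0.89 ± 0.44 (adjusted p = 0.692 over all genes). Markers of B cells and plasma cells, which share 3 genes with the early lymphoid list, rose with a median of 0.55 (camera adjusted p = 0.000407; adjusted p = 0.950 with an estimated correlation). All 13 measured members were higher and none was called over all genes or adjusted over the list alone. Cd79a, with 1.70 ± 0.50 (SE), is among them. Neutrophil markers moved the same way, with a median of 2.39.

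Ribosomal protein genes rose by a median of 0.18 (camera adjusted p = 0.00165; adjusted p = 0.950 with an estimated correlation), but their median was -0.03 after quantile normalization and -0.04 after scaling to the array median, where the call was lost. Of 32 members 29 were higher, with the largest differences in Rps3 (0.59) and Rps7 (0.53), and none was called. The call was also lost without knockout-labelled replicate 1 (adjusted p = 0.395) and without control replicate 2 (adjusted p = 0.424). DNA repair genes fell as a group, with a median of -0.30 (camera adjusted p = 0.0318; adjusted p = 0.950 with an estimated correlation) and 16 of 20 members lower. Among them, Atr, a checkpoint kinase gene, differed by -0.73 ± 0.28 (SE), while Lig4 lay under the array's 30th percentile in control replicate 1 and its size is not given. The DNA repair call was lost without each array in turn, with adjusted p from 0.0673 (without control replicate 2) and 0.0950 (without control replicate 1) to 0.0990 and 0.149 (without knockout-labelled replicates 2 and 1), while the median stayed between -0.38 and -0.21. Enzymes of DNA and histone methylation fell, with a median of -0.22 (camera adjusted p = 0.0415; adjusted p = 0.950 with an estimated correlation) and 15 of 18 members lower. Kdm1a, a lysine demethylase gene, differed by -0.75 ± 0.24 (SE) and the DNA methyltransferase gene Dnmt3b by -0.50 ± 0.23. This call was lost without knockout-labelled replicate 2, where the median was -0.05, and without control replicate 1, where it was -0.18. No member of these 3 lists was called over all genes or adjusted over the list alone. Neutrophil markers differed by a median of 2.39 between the same arrays.

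**Figure D3:**
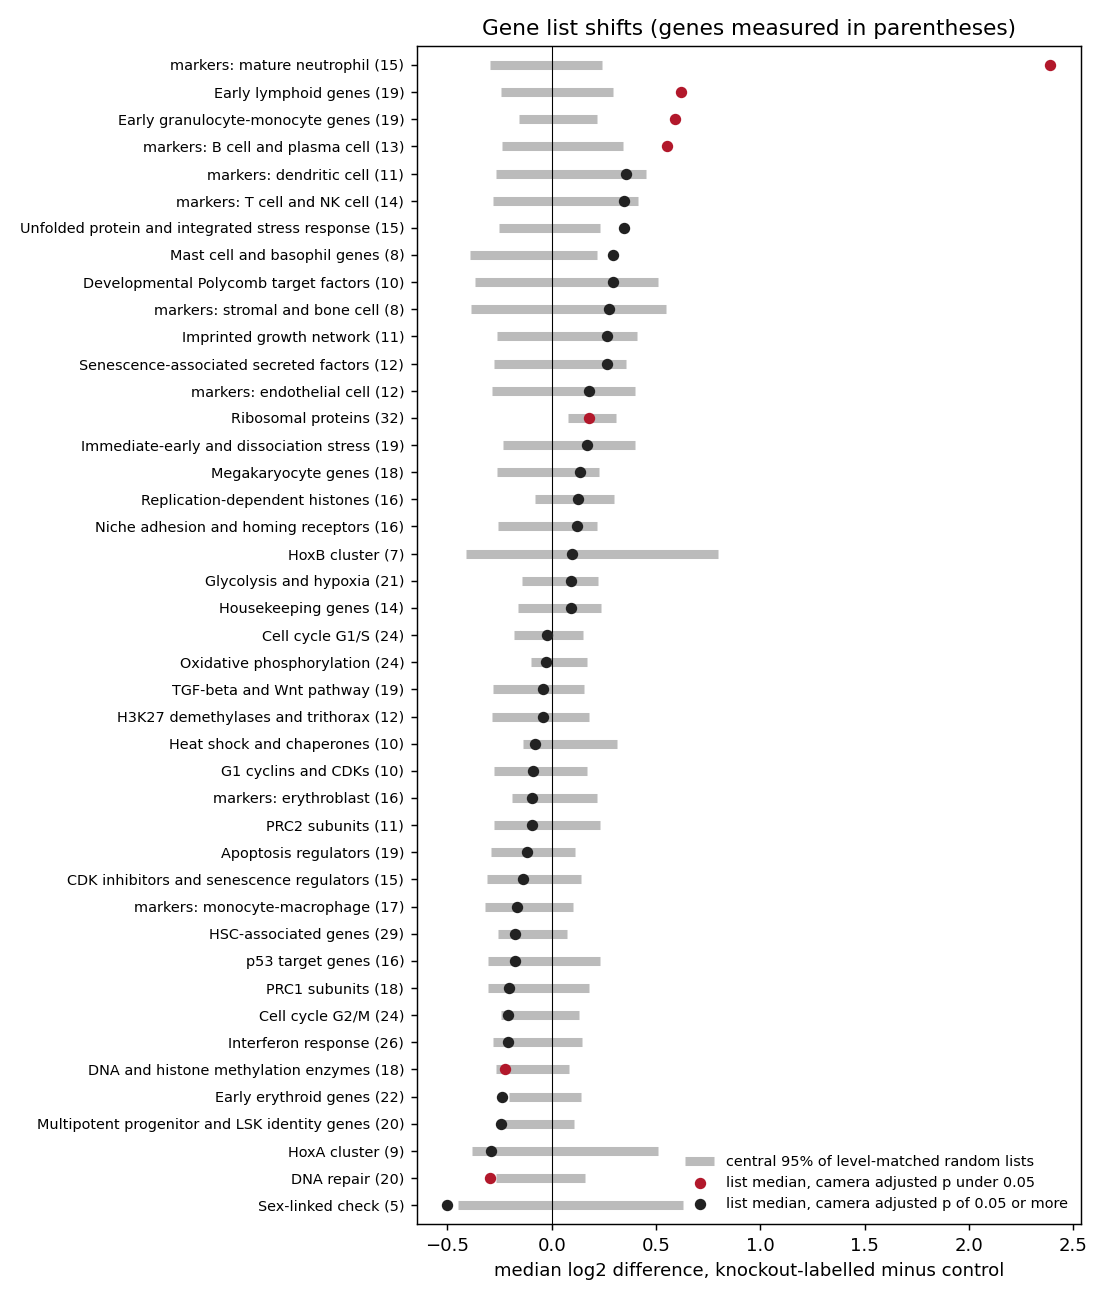
Median log2 difference of each tested gene list, knockout-labelled minus control, with grey bars for the central 95% of medians of 10000 random lists of like mean expression. The neutrophil marker list lies at 2.39, and the early lymphoid, early granulocyte-monocyte and B cell lists lie at 0.62, 0.59 and 0.55, beyond their grey bars, as do DNA repair and 5 lists that did not pass camera.

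The other 36 tested lists did not pass, with medians between -0.50 and 0.36. Of these, the unfolded protein response (0.35), mast cell (0.29), early erythroid (-0.24), LSK identity (-0.24) and sex-linked (-0.50) lists lay beyond the central 95% of random lists of like expression. PRC2 subunits had a median of -0.10 (camera adjusted p = 0.388) with 4 of 11 members higher. Ezh2, the paralog of Ezh1, differed by -0.49 ± 0.30 (SE; adjusted p = 0.692), the core subunit genes Eed by -0.37 and Suz12 by -0.10, Jarid2 by -0.60, Aebp2 by -0.40 and Mtf2 by -0.40. Rbbp4, Rbbp7, Phf1 and Phf19 differed by -0.03, 0.02, 0.33 and 0.12. PRC1 subunits had a median of -0.20 (adjusted p = 0.357), with -0.92 for Pcgf6; Cbx8 lay under the array's 30th percentile in control replicate 2, so its size is not given. H3K27 demethylases and trithorax genes had a median of -0.04 (0.535), with -0.69 for Kdm6a and -0.62 for Kmt2c. The developmental Polycomb target factors, of which 10 of 47 could be measured, had a median of 0.29 (0.271), with 1.29 for Hand1 and 0.59 for Lhx1. The HoxA cluster had a median of -0.29 (0.357), with -0.56 for Hoxa2 and 0.47 for Hoxa13. The HoxB cluster had a median of 0.10 (0.596), but Hoxb9 in both controls and Hoxb8 in control replicate 2 lay under the array's 30th percentile, so their sizes are not given. The HoxC and HoxD clusters had 3 measured genes and were not tested; all 3 were higher. Hoxc4 differed by 1.15, and Hoxc5, whose value is the list median, lay under the 30th percentile in knockout-labelled replicate 1, so its size and the median are not given. The imprinted growth network had a median of 0.27 (0.273), with 0.70 for H19 and 0.66 for Ndn.

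Genes of growth arrest did not pass either. CDK inhibitors and senescence regulators had a median of -0.14 (camera adjusted p = 0.831). The inhibitor genes Cdkn1a and Cdkn1c differed by 0.41 ± 0.30 (SE) and 0.27 ± 0.31, and Hmga2 by 0.38. Cdkn2a, the Ink4a/Arf gene, did not pass the dim filter. Its brighter probe, A_55_P2008437, read 18.9 and 179 intensity units in the knockout-labelled arrays and 7.49 and 56.7 in the controls, so that the arrays of number 2 were the brighter in both groups. Senescence-associated secreted factors had a median of 0.26 (0.141), with 1.19 ± 0.60 (SE) for Il1b; Mmp12 lay at the floor in control replicate 1 (-7.71), so its size is not given. Genes induced by p53 had a median of -0.18 (0.642), with 1.17 for Plk2 and -1.06 for Tnfrsf10b. The G1/S list had a median of -0.02 (0.474), with -0.63 for Pola1 and -0.59 for E2f1. The G1 cyclins and CDKs had a median of -0.09, a mean of 0.01 and an adjusted p of 0.885, with 0.60 for Ccnd1 and 0.41 for Ccnd3. The G2/M list had a median of -0.21 (0.474), but its member Cdk1, the mitotic kinase gene, rose by 1.70 ± 0.29 (SE; limma adjusted p = 0.0230 over the list alone). Only the brightest of the 3 Cdk1 probes showed this, and the others differed by 0.17 and -0.56. Replication-dependent histones had a median of 0.13 (0.474), with -1.09 for H2bc8 and 0.68 for H4c8. Apoptosis regulators had a median of -0.12 (0.474), with 0.55 for Pmaip1 and 0.47 for Birc2. Without control replicate 1 the histone list passed (adjusted p = 0.0450, higher).

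Genes of stem cell and LSK identity had medians slightly below 0 without passing the test. HSC-associated genes had a median of -0.17 (camera adjusted p = 0.273) and 9 of 29 members higher, with -0.76 for Ctnnal1 and 0.69 for Ly6a, the gene of Sca-1. Multipotent progenitor and LSK identity genes had a median of -0.24 (0.141) and 5 of 20 members higher, with -0.44 ± 0.24 (SE) for Kit, -0.28 ± 0.21 for Flt3 and -0.81 ± 0.24 for Angpt1. The HSC-associated median was -0.34 without knockout-labelled replicate 1 and -0.46 without control replicate 2. It was above 0 without knockout-labelled replicate 2 (0.06) and without control replicate 1 (0.03). The multipotent progenitor median was -0.39 without knockout-labelled replicate 1. Early erythroid genes had a median of -0.24 (0.388), with 0.91 for Ermap and -0.73 for Rhag. Megakaryocyte genes had a median of 0.14 (0.475), with 1.30 for Alox12 and 1.25 for Clec1b. Mast cell and basophil genes had a median of 0.29 (0.475), with 1.66 ± 0.78 (SE) for Prss34 and 1.22 ± 0.51 for Mcpt8. Both read higher in knockout-labelled replicate 1 (2.56 and 2.49) than in replicate 2 (-0.01 and 0.84). The list median was 0.54 without knockout-labelled replicate 2 and 0.38 without replicate 1, where the sign of its test changed. Among markers of other cell types a marrow sort could hold, monocyte and macrophage genes had a median of -0.17 but a mean of 0.07 (0.716), and 1 member, the lysozyme gene Lyz2, rose adjusted over the list alone (1.28 ± 0.24, SE; limma adjusted p = 0.0274). Erythroblast markers had a median of -0.10 (0.725), with 0.75 for the beta globin gene Hbb-b2. T cell and NK cell markers had a median of 0.35 (0.0735), and Il2rb, a cytokine receptor chain, rose adjusted over the list alone (1.65 ± 0.30, SE; limma adjusted p = 0.0177). Dendritic cell markers had a median of 0.36 (0.480), with 1.07 for Ccr9. Stromal and bone markers had a median of 0.27 (0.480), with 1.38 for Cxcl12 and 0.93 for Sparc, and endothelial markers 0.18 (0.642), with 1.43 for Flt1. Batf3 in control replicate 2 and Flt4 in control replicate 1 lay under the array's 30th percentile, so their sizes are not given. In the sex-linked list, which had the lowest median (-0.50; 0.475), Xist differed by 0.84 and Uty by -0.74, and Y-linked genes gave signal in all 4 arrays. Without control replicate 2, early erythroid genes and erythroblast markers had medians of -0.51 and -0.48, and monocyte and macrophage markers -0.46. Without control replicate 1 these medians were 0.13, 0.31 and 0.44, so their direction depended on which control array was left out. The T and NK cell median was 0.20 without knockout-labelled replicate 2.

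Stress and metabolic lists also stayed short of the threshold. The interferon response list had a median of -0.21 (camera adjusted p = 0.0586) and 19 of 26 members lower. Adjusted over the list alone, 1 member fell, Rsad2 (-2.29 ± 0.21, SE; limma adjusted p = 0.000774), and 1 rose, Zbp1, a nucleic acid sensor gene (1.29 ± 0.24; limma adjusted p = 0.0193). Genes of the unfolded protein and integrated stress response had a median of 0.35 (0.0769), with 0.85 ± 0.39 (SE) for Xbp1; Chac1 lay at the floor in control replicate 1 (-7.71), so its size is not given. Immediate-early and dissociation stress genes had a median of 0.17 (0.271), with 1.37 for Junb; Egr3 lay under the array's 30th percentile in control replicate 2, so its size is not given. Heat shock genes and chaperones had a median of -0.08 (0.725), with -0.39 for Dnaja1 and 0.38 for Hspe1. Oxidative phosphorylation genes had a median of -0.03 and a mean above 0 (0.868); Atp5o, a subunit gene of ATP synthase, rose adjusted over the list alone (1.07 ± 0.21, SE; limma adjusted p = 0.0453). Glycolysis and hypoxia genes had a median of 0.09 (0.642), with -0.73 for Pdk1 and -0.51 for Bnip3. TGF-beta and Wnt genes had a median of -0.04 (0.475), with 0.81 for Lrp5 and -0.74 for Tgif1. Niche adhesion and homing receptors had a median of 0.12 (0.716), with 0.80 for Cdh2 and -0.62 for Itga5. Housekeeping genes had a median of 0.09 (0.817), with -0.50 for Tbp and -0.49 for Sdha. Without control replicate 1 the interferon list (adjusted p = 0.00592, lower), the unfolded protein response list (0.0117, higher) and oxidative phosphorylation genes (0.0450, higher) passed.

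The authors' deposited table of fold changes gives a size, a direction and a p for each probe. In the authors' deposited table, 1975 probes were up and 1298 down at an unadjusted p under 0.05, and 937 up and 186 down with a fold of at least 2 besides. After Benjamini-Hochberg adjustment of the p in the authors' deposited table, 0 probes passed 0.05 and the smallest value was 0.156. The log2 differences computed here had the same sign for 99.96% of probes and differed from those of the authors' deposited table by at most 0.0025. In the authors' deposited table the brightest Ezh1 probe was up by 1.21-fold (p = 0.137) and the dimmest down by 2.22-fold (p = 0.347).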

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

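All alternatives were planned. With 1 array left out, the lone array of its group was assumed to vary like the other group. The main limma fit called 0 genes, with 1198 at an unadjusted p under 0.05. The number called stayed 0 after quantile normalization, with 50 added, without the dim filter, with the mean of a gene's probes, without the trend, with array weights and with every probe on its own. It was 104 (99 higher) after median scaling, 7 (6 higher) with the stricter dim filter and 2 to 626 with 1 array left out. The plain equal-variance test gave 246 (206 higher) at an unadjusted p under 0.05 with a 2-fold minimum, which is not an adjusted count, and 0 after adjustment. With the replicate number as a block it was 142 (136 higher), including 8 of the neutrophil markers. Nothing in the labels pairs the arrays by number, yet the differences between replicates 1 and 2 of each group correlated across genes at r of 0.705. In each group the array of number 1 also had the wider log2 signal distribution. Genes at least 2-fold higher or lower without overlap, 740 and 173, were 560 and 419 after quantile normalization, 493 and 473 after median scaling, 565 and 77 with 50 added, 1521 and 318 without the dim filter, 411 and 98 with the stricter one, and 678 to 2636 higher and 276 to 683 lower with 1 array left out. The filters changed the number of genes tested, from 17090 to 24231 without the dim filter and 13192 with the stricter one. The counts of higher genes changed by more than in proportion to it. With 1 array against 2, chance parts 66.7% of genes rather than 33.3%, which can raise such counts by construction. That alone does not account for the number higher, which fell to 678 without control replicate 1. The other causes were not tested. The Ezh1 difference of 0.27 was 0.05 after median scaling and 0.16 to 0.39 with 1 array left out. With the mean of its probes, which takes in the dimmest probe, it was -0.21. The number of lists called, 7, was 4 after median scaling, 0 with an estimated correlation, 0 by fry (smallest adjusted p 0.204), and 6 to 10 with 1 array left out. With an estimated correlation the adjusted p of each of the 7 was 0.950. By fry it was 0.204 for neutrophil markers, 0.334 for early granulocyte-monocyte genes, 0.839 for early lymphoid genes, 0.345 for B cell markers and for DNA repair, and 0.944 for ribosomal proteins and methylation enzymes. Ribosomal proteins had 0.718 after quantile normalization and 0.532 after median scaling. DNA repair had 0.214 after median scaling and 0.0768 with the stricter filter. Methylation enzymes had 0.0630 after quantile normalization, 0.214 after median scaling, 0.133 with the stricter filter and 0.0840 without the trend. With 1 array left out the adjusted p ranged from 3.00e-42 to 6.32e-12 for neutrophil markers, 2.79e-14 to 5.96e-05 for early granulocyte-monocyte genes, 8.54e-05 to 0.0384 for B cell markers, 1.36e-15 to 0.428 for early lymphoid genes, 6.52e-06 to 0.424 for ribosomal proteins, 0.0673 to 0.149 for DNA repair and 0.0189 to 0.649 for methylation enzymes. The causes were not tested. Among the 36 lists not called, 17 changes put a list past the threshold, 53 changed the sign of its test without passing, and 1 did both. Oxidative phosphorylation genes, with a median of -0.03, went the other way past the threshold without control replicate 1 (adjusted p = 0.0450, median 0.20), over a range to 0.814 with 1 array left out; they had 0.0298 (lower) after quantile normalization and changed sign with the stricter filter (0.886). Other lists past the threshold were multipotent progenitor genes (0.0256), T and NK cell markers (0.0375) and interferon response (0.0115) without the dim filter, and T and NK cell markers (0.0356) and the unfolded protein response (0.0378) with the mean of probes. Signs changed after quantile normalization for glycolysis (0.620), histones (0.708) and housekeeping genes (0.480); after median scaling for monocyte markers (0.897), glycolysis (0.637), histones (0.831), niche receptors (0.832) and housekeeping genes (0.723). They changed without the dim filter for G1 cyclins (0.950), niche receptors (0.960) and housekeeping genes (0.912), and with the stricter filter for CDK inhibitors (0.936) and G1 cyclins (0.921). With 1 array left out, some lists passed in part of their range: HSC-associated genes (0.00958 to 0.956), multipotent progenitor genes (0.0461 to 0.921), early erythroid genes (0.00382 to 0.952), mast cell and basophil genes (3.19e-05 to 0.893), monocyte markers (0.000744 to 0.991), erythroblast markers (0.00958 to 0.806), T and NK cell markers (0.0414 to 0.255), interferon response (0.00592 to 0.212), the unfolded protein response (0.0117 to 0.412) and histones (0.0450 to 0.710). Others changed sign without passing: PRC1 (0.0915 to 0.970), H3K27 demethylases and trithorax (0.130 to 0.956), CDK inhibitors (0.312 to 0.991), p53 targets (0.279 to 0.988), megakaryocyte genes (0.155 to 0.991), dendritic cell (0.430 to 0.989), stromal (0.240 to 0.991) and endothelial markers (0.485 to 0.991), G1/S (0.130 to 0.746), G2/M (0.378 to 0.874), G1 cyclins (0.157 to 0.802), apoptosis (0.162 to 0.991), heat shock (0.212 to 0.956), HoxB (0.107 to 0.778), developmental factors (0.151 to 0.972), glycolysis (0.155 to 0.893), TGF-beta and Wnt (0.212 to 0.996), niche receptors (0.366 to 0.645) and housekeeping genes (0.297 to 0.676). The causes were not tested. Of the genes named, 99 changes put a gene past the threshold and 25 changed its sign without passing. Not run were the value table, for its probe names, a background correction, for want of background values, and a slide block, for want of slide numbers. Signal over background could not be measured; the dim filter stood in for it.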

Other observations

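The tests of equal rises of other cell types, of Ezh1 transcript and of ribosomal protein signal were chosen after the result was seen. The genes named in this paragraph outside the lists were also chosen after their values were seen. The predicted gene Gm3219 read 786 and 1425 intensity units in the knockout-labelled arrays against 13.0 and 10.2 in the controls (limma adjusted p = 0.175), where the control values lie near the floor, so that no size is given. In the interferon list Rsad2 (-2.29) and Zbp1 (1.29) went opposite ways. Of the G2/M list, 8 genes were higher and 16 lower, with Hmmr at 1.03 and Cdk1 at 1.70 by its brightest probe, but at 0.17 and -0.56 by its others. Component 1, with 76.6% of the variance, parted the arrays by replicate number: control and knockout-labelled replicates 1 lay at -101 and -5.19, and replicates 2 at 29.9 and 76.7. In this same order the interquartile range of the log2 signal narrowed, with 5.95, 4.93, 4.22 and 3.83. Replicate number and width of the signal distribution can therefore not be told apart here. Component 2, with 15.0%, parted the groups, with -39.1 and -9.19 for the knockout-labelled arrays and 7.16 and 41.1 for the controls.

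Neutrophil marker genes had a median log2 difference of 2.39, and early granulocyte-monocyte genes 0.59, each at percentile 100 of 10000 random lists of like expression, which argues against distortion by signal level as the whole cause. Markers of other cell types did not rise equally in log2 units, by tests written after the medians of these lists were known. Mixed-in cells need not raise all markers equally, since markers already bright in the controls can rise little. These tests therefore do not decide whether other cells were mixed in. The neutrophil median exceeded that of pooled erythroblast, monocyte-macrophage and T and NK cell markers by 2.37 (permutation of genes between lists, p = 1e-05, the smallest these permutations can give). Among markers of low control signal it exceeded that of 8 other lists by 1.73 (same permutation, p = 6e-05). These permutations treat genes as independent and do not measure the spread between arrays. Of those 47 other markers 36 were higher (median 0.40, against 0.14 for all other genes under the same filter), so a smaller or unequal rise of other types stays open. RNA of mature neutrophils in the knockout-labelled sorts is a candidate explanation for the neutrophil markers. It was not tested for the early granulocyte-monocyte genes. A separate list of 25 transcripts abundant in neutrophils was written before its test but after the values of Clec4e, Cxcr2 and Csf3r had been seen. It had a median of 0.47 at percentile 99.99, with 19 higher (10 of them without overlap) and 6 lower (3 of them without overlap). However, 12 of the 25 lay above the 75th percentile in both controls and 2 are on the other lists. Of 11 members under the 75th percentile in both controls, where such RNA would show most, 8 were higher, among them Asprv1 (1.04) and Cd14 (0.90), whose groups overlapped. The 3 lower were Clec4e (-1.51), Fpr1 (-0.10) and Il1r2, which lay under the 30th percentile in knockout-labelled replicate 2. Under the same filter 57.8% of all other genes and 36 of 47 other markers were higher, so 8 of 11 does not speak for neutrophil RNA in particular. A lineage gate would remove such cells, S100a9 read 3.93 and 3.80 against 1.11 and 0.40, and a response to genotype and the amplification cycles stay open, neither of them tested.

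Early lymphoid genes (median 0.62) and B cell markers (0.55) lay at percentiles 100 and 99.71 of random lists of like expression, which argues against signal level as the whole cause. Ribosomal protein genes lay at percentile 52.14, with 0.18 against a median of 0.17 for equally bright genes, so that their call may reflect signal level alone. DNA repair genes lay at percentile 1.16 and methylation enzymes at 7.39, the latter within the central 95%. The early lymphoid call was lost without knockout-labelled replicate 1 (adjusted p = 0.428, over a range from 1.36e-15 to 0.950 across all alternatives), and an effect of genotype stays open and untested.

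The brightest Ezh1 probe was not lower in the knockout-labelled arrays (0.27), whereas the dimmest was lower in both of them (limma adjusted p = 0.685), with a reading under the array's 30th percentile in knockout-labelled replicate 2 that the mean of the probes (-0.21) takes in. A transcript kept from the targeted allele at the probed part and a wrong label cannot be told apart with these values, since the deleted part is not given in the sources used here. A flank of the targeted allele from another strain could leave differences near the gene: 9% of the 100 genes nearest to Ezh1 had an unadjusted limma p under 0.05, against 7.0% of 16989 elsewhere (Fisher's exact p = 0.428), which left this open.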
